A study of Homo sapiens with 9 samples.

How the data were processed

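Gene expression was measured in an insulin-resistant form of HepG2, a human hepatoma line, named R-HepG2 in the labels, on 9 one-colour Affymetrix expression arrays. Per the labels' protocols, cells were kept without serum overnight and then given plain medium, insulin or biomineralized insulin for 4 h, both insulin preparations at 40 ug/ml. Total RNA was converted to biotin-labelled cRNA with a 3' in vitro transcription kit, per the labels' protocols, so the arrays read mainly the 3' ends of messenger RNA. Groups and replicate numbers were taken from the sample titles, which give 3 replicates in each of 3 groups. The cell line tag reads R-HepG2 for the medium samples and HepG2 for the treated samples, and the design text also speaks of treated HepG2, while the growth and treatment protocols describe R-HepG2 throughout. The protocols were followed here. If the treated cells were another form of the line than the medium cells, comparisons with medium would hold that difference too. No source used here says whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. No group received the mineral component without insulin, so its effect and that of the insulin are not separated.

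The deposited values are log2 expression values per probe set, as found from their range of 2.02 to 14.3 and their near-identical distributions on the 9 arrays. The authors' summarisation and normalization software is not given in the sources used here. Scanner files were not used here, so background and detection calls were not examined. The number of arrays limits the precision. Of 49395 probe sets, 44994 had 1 gene symbol in the platform annotation, 1832 had several, 2473 had none listed there and 102 were control features. Symbols were brought up to date through Entrez identifiers with the RefSeq gene table of assembly GRCh38.p14 for 44967 probe sets, and 27 kept the symbol of the annotation. No coordinates are given, because the build behind the array is not given in the sources used here.

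Choices of test, filters, gene lists and the rule for named genes were made before the data were examined. Probe sets in the dimmest 40 percent by mean over the 9 arrays (below 4.74 log2) were left out, and each gene was represented by its probe set with the highest mean among those with 1 gene, which left 12240 genes of 18132 with any such probe set. Several probe sets were available for 7151 of the tested genes. All 9 arrays entered one limma model (limma 3.58.1, R 4.3.3, lmFit and eBayes with an intensity trend, 6 residual degrees of freedom) without a replicate term, and 3 contrasts were taken. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes are called changed. Gene lists fixed beforehand (26) were tested with camera at a preset correlation of 0.01, adjusted within each comparison. Camera with an estimated correlation and fry were alternatives. Counts over all tested genes are also given adjusted over the list alone. Genes named are the 8 largest rises and 8 largest falls per comparison among called genes whose 3 values in one group all lie above those of the other, leaving out unnamed loci, up to 4 members with the lowest p of each list that passed its test or had at least 3 changed members, and fixed insulin and FOXO1 marker genes. Where other genes are named, the text says so.

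Same-numbered arrays did not deviate together, so the numbers were not taken to pair arrays. Comparisons against the same medium arrays were set beside 100 simulations of unchanged groups sharing those controls, and, after the data were seen, 100 for genes selected in insulin against medium. Control features on the arrays were compared with exact permutation tests over 16 tests. The whole procedure was tested on simulated data drawn from the real means and spreads with 200 changed genes. In insulin against medium, changes of 0.2, 0.4 and 0.8 log2 were recovered for 32.8, 83.6 and 98.5 percent of genes, with 4 false calls among 12240 genes. In biomineralized insulin against medium the shares were 28.4, 71.6 and 93.9 percent with 7 false calls, and in biomineralized insulin against insulin 32.8, 77.6 and 98.5 percent with 7 false calls. A simulated list of 20 genes among 26 lists shifted by 0.15 log2 in biomineralized insulin against medium was found at both correlation settings. Simulated genes varied independently of each other, while the estimated correlation within the real lists reached 0.38 (hypoxia targets). Neither the false calls nor the list test therefore cover correlated genes. Alternatives covered the replicate block, the arrays in the fit, normalization, an offset, brightness filters, the choice of probe set, the variance model, array weights, thresholds and leaving out each array. Centring on the poly-A spike-ins was added after the data were seen. The 12 genes plotted per array were chosen after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.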

Results

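Messenger RNA was measured on 9 arrays in insulin-resistant cells of the hepatoma line HepG2, after 4 h in plain medium, in insulin or in biomineralized insulin. The cell line tags name the resistant form for the medium arrays and HepG2 for the treated arrays, while the protocols name the resistant form for all. Each group had 3 arrays, and both insulin preparations were given at 40 ug/ml. The series title places the study in the setting of insulin acting inside the nucleus and of epigenetic change in insulin resistance. The medians of the arrays lay between 5.46 and 5.50 log2. Arrays of one group correlated at 0.998 to 0.999 across probe sets, and pairs from different groups at 0.984 to 0.998. The first principal component held 78.4% of the variance and separated the 3 biomineralized insulin arrays from the other 6.

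Which transcripts respond to soluble insulin in these cells was asked by comparing insulin with medium. Transcripts moved by small amounts. MSMO1, a sterol methyl oxidase, rose by 0.41 ± 0.06 log2 (SE, 3 arrays against 3, adjusted p = 0.0031), although without cross-hybridizing probe sets MSMO1, insulin against medium, was at 0.09 (adjusted p = 0.73, in a range of 0.00094 to 0.73 over all alternatives). SQLE, squalene epoxidase, rose by 0.32 ± 0.05 (adjusted p = 0.0053). INSIG1, a sterol-regulated protein that holds back sterol synthesis, rose by 0.36 ± 0.07 (adjusted p = 0.011). ASNS, asparagine synthetase, fell by 0.31 ± 0.04 (adjusted p = 0.0019), and PHGDH, the first enzyme of serine synthesis, fell by 0.18 (adjusted p = 0.025). The 2 genes that changed by at least 1.5-fold both fell: NIBAN1, a stress-responsive gene, by 0.61 ± 0.06 log2, and GDF15, a stress-induced secreted factor, by 0.60 ± 0.09, whose weakest of 5 probe sets was at -0.070. Of 12240 genes, 300 passed the adjusted threshold, 153 higher and 147 lower, with a median change of 0.21 log2, and 1928 had an unadjusted p under 0.05. The 3' minus 5' signal of actin, a control for RNA quality, was 3.19 ± 0.08 log2 on insulin arrays and 3.02 ± 0.06 on medium arrays (SD, n = 3), a difference of 0.17 with every insulin array above every medium array (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, and 0.267 adjusted over 16 tests), while that of GAPDH differed by 0.0042 (exact p = 0.8). Among the largest rises were PPFIA4 (0.50 log2, weakest probe set 0.094), ARNT2 (0.50, weakest probe set 0.067), GABRE (0.47) and B4GALNT4, whose medium mean of 4.45 lay below the brightness filter of 4.74 and whose insulin mean was 4.92, and among the largest falls were BEX2 (-0.55), SYNE1 (-0.54), IFIT2 (-0.50) and PCDH9 (-0.44, with 1 of its 3 probe sets of opposite sign).

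Lists of sterol synthesis, fatty acid synthesis and hypoxia genes shifted upwards under insulin, on the arrays with the higher actin 3' minus 5' signal. Of 20 measured cholesterol synthesis genes, 5 rose over all genes tested, and 6 rose adjusted over the list alone. The list passed camera at adjusted p = 1.0e-05, but adjusted p = 0.21 with an estimated correlation. Of 21 fatty acid synthesis genes, 4 rose (adjusted p = 0.0068, and adjusted p = 0.21 with an estimated correlation), with 4 adjusted over the list alone. These were INSIG1, also counted among the sterol genes, LPIN1, ELOVL6 (weakest probe set 0.047 log2) and SCD, the fatty acid desaturase, which rose by 0.12 log2 while 2 of its 4 probe sets had the opposite sign. With the mean of each gene's probe sets that list did not pass (adjusted p = 0.18). Of 26 hypoxia targets, 1 rose, ADM, the gene of adrenomedullin, by 0.21 log2, and 4 did so adjusted over the list alone. That list passed at adjusted p = 0.0068, but adjusted p = 0.78 with an estimated correlation, and for the list hypoxia (HIF1A) targets, insulin against medium, the adjusted p was 0.17 without medium replicate 2 and 0.37 without insulin replicate 3, in a range of 9.3e-05 to 0.78 over all alternatives. In the unfolded protein and integrated stress response list of 36, 5 fell and 1, MANF, rose, and the list did not pass (adjusted p = 0.13). The lists of immediate early genes, cell cycle genes and DNA methylation and histone modifiers did not pass (adjusted p = 0.59, 0.32 and 0.59). The marker genes INSR, IRS1, IRS2, SREBF1, FASN, EGR1, SOCS3, PPARGC1A and DNMT1 were not called, with changes between -0.04 and 0.16 log2, and 1 probe set each of EGR1 and PPARGC1A had the opposite sign. The marker gene TRIB3, insulin against medium, was called at -0.14 ± 0.04 log2 (adjusted p = 0.0496), and the call was lost when any single array other than insulin replicate 2 was left out (adjusted p = 0.064 to 0.27), in a range of 0.013 to 0.9999 over all alternatives.

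The number of genes changed, insulin against medium, was 300 with all arrays, 187 without medium replicate 1, 62 without medium replicate 2, 145 without insulin replicate 1 and 57 without insulin replicate 3, 37 with a variance model without the intensity trend, 425 without insulin replicate 2 and 604 with array weights. It was also 152 with only the 6 arrays compared, 190 with median centring, 177 with the probe set of largest variance, 199 without cross-hybridizing probe sets and 7 when arrays were centred on the poly-A spike-in controls, a setting chosen after the data were seen. The calls of INSIG1, PHGDH, PPFIA4, B4GALNT4, SCD, ADM, LPIN1 and ELOVL6 were lost without insulin replicate 3, from adjusted p = 0.054 (ADM, insulin against medium) to adjusted p = 0.22 (ELOVL6, insulin against medium), and all of these but B4GALNT4 also without medium replicate 2. Other splits of the same 6 arrays into 3 and 3, which mix insulin and medium, gave up to 185 called genes.

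Biomineralized insulin against medium asked how this preparation changes the same transcripts. INHBE, an activin subunit gene, was at least 29.1-fold lower (adjusted p = 5.1e-17), at 9.60 ± 0.07 log2 in medium and 4.32 ± 0.22 with biomineralized insulin (SD, n = 3 arrays), and FGF21, a hepatokine gene, at least 6.87-fold lower, at 7.52 and 3.78. Both means with biomineralized insulin lay below the brightness filter of 4.74 log2, and the bounds are against that level, which is not a measured background. SLC7A11, the cystine transporter, fell by 3.18 ± 0.04 log2 (weakest probe set -0.80). The transcription factor genes ATF3 and DDIT3 changed by -3.02 ± 0.08 and -2.90 ± 0.06, with -0.43 for the weakest probe set of ATF3. PCK2, mitochondrial phosphoenolpyruvate carboxykinase, fell by 2.65 ± 0.06, and ECM2 and STC2 changed by -2.80 and -2.70. HSPA1B, a stress-induced heat shock protein 70 gene, rose by 2.84 ± 0.06 log2 (7.15-fold), although its near-identical copy HSPA1A may share this signal. HSPA8, the constitutive member of that family, rose by 1.86 ± 0.04 (weakest probe set 1.08), and INSIG1 by 1.78 ± 0.07 (weakest probe set 0.67). FGFBP1, SPOCK1, CEMIP and SPINK6 rose by 1.85, 1.76, 1.73 and 1.67 log2, although another probe set of CEMIP was at 0.11. RPL27A, read by 1 probe set, rose by 1.78 from 5.34 ± 0.30 log2 in medium (SD, n = 3 arrays). On those arrays the median of 66 ribosomal protein genes was 13.5 log2.

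**Figure D1:**
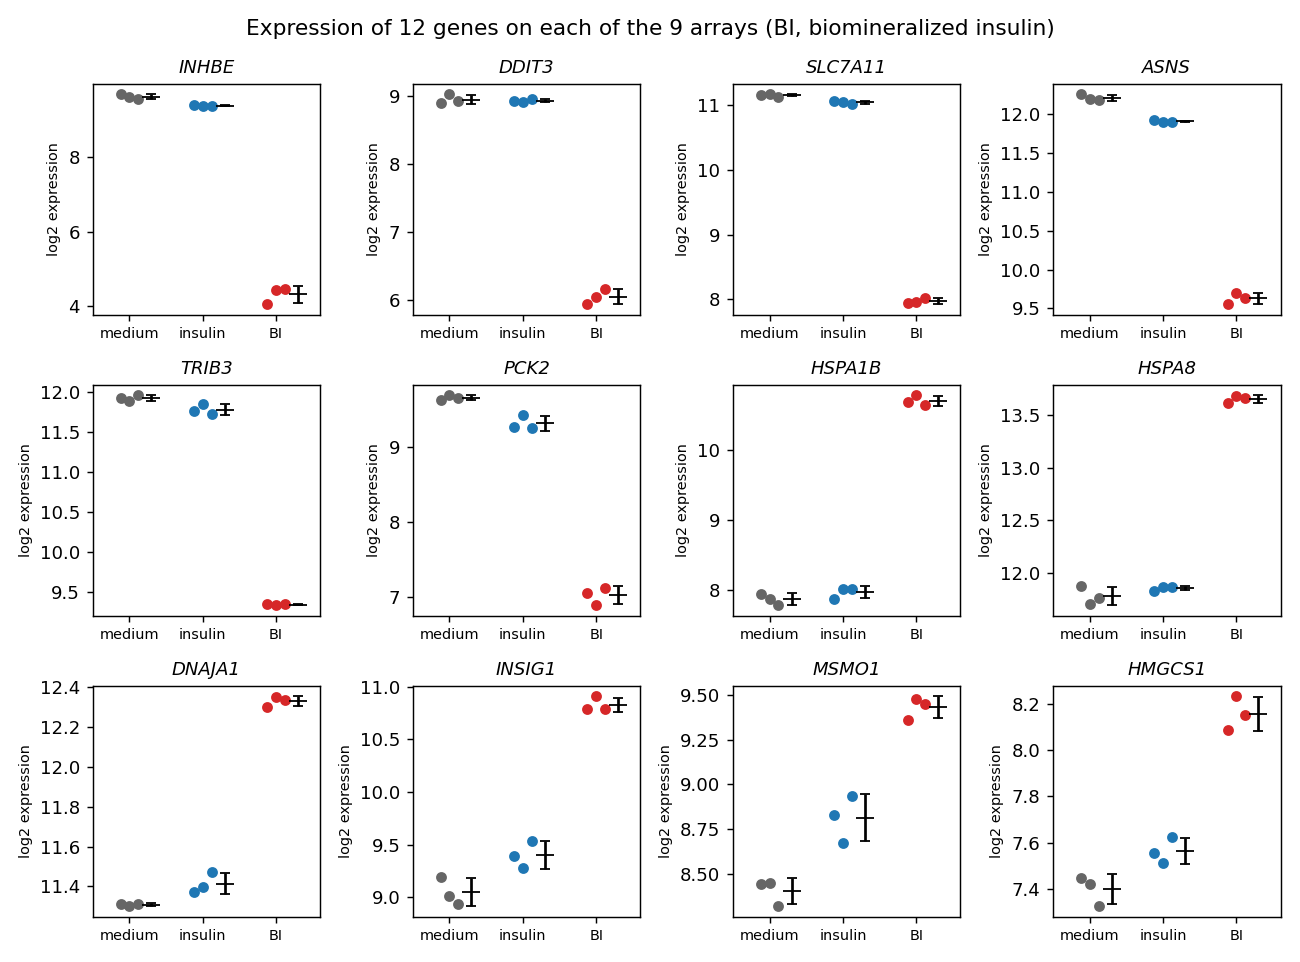
Log2 expression (vertical axes, one scale per gene) of 12 genes on each of the 9 arrays by group, with horizontal marks for the mean and bars for the SD of 3 arrays. INHBE, DDIT3, SLC7A11, ASNS, TRIB3 and PCK2 lie lower on the 3 biomineralized insulin arrays, and HSPA1B, HSPA8, DNAJA1, INSIG1, MSMO1 and HMGCS1 higher, than on the other 6 arrays.

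The number of genes changed, biomineralized insulin against medium, was 6230 of 12240, 3140 higher and 3090 lower. At least 1.5-fold was reached by 870 of them (338 higher, 532 lower), and 2-fold by 200 (58 higher, 142 lower). On the biomineralized insulin arrays the poly-A spike-in controls, bacterial transcripts added to the RNA, were brighter by 0.40 log2 than on medium arrays. When arrays were centred on these controls, a setting chosen after the data were seen, the median of all genes moved by -0.40 log2 and the count became 9393, with 273 higher and 9120 lower. Directions in this and the next comparison therefore describe change relative to the median of all genes.

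**Figure D2:**
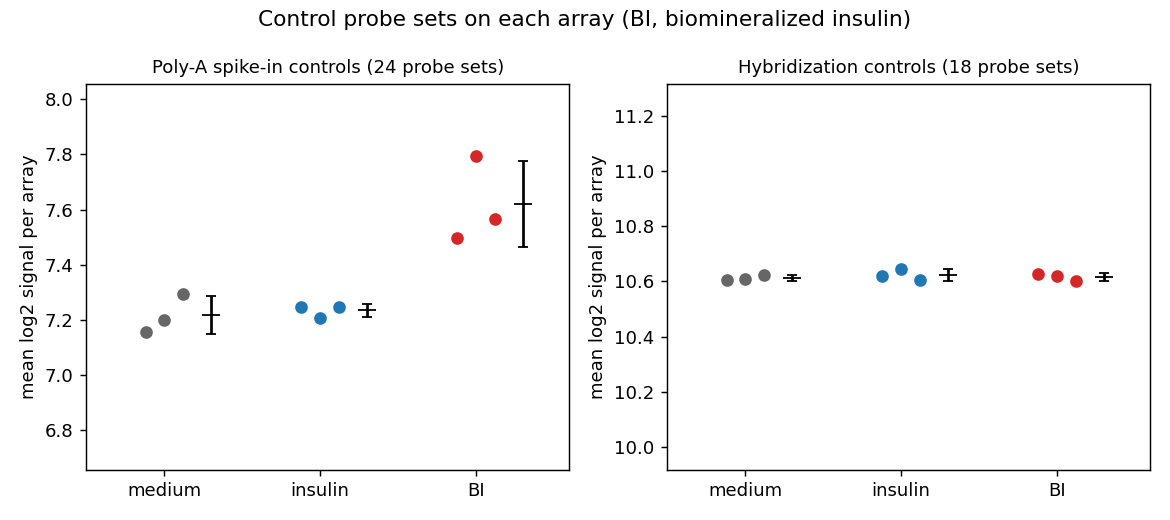
Mean log2 signal per array of the 24 poly-A spike-in probe sets (left) and 18 hybridization control probe sets (right), by group, with marks for the mean and bars for the SD of 3 arrays. The spike-in means of the 3 biomineralized insulin arrays lie above those of the other 6, with a group mean of 7.62 against 7.22 in medium, while hybridization controls lie between 10.60 and 10.65 on all arrays.

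Within the unfolded protein and integrated stress response list, 20 of 36 genes fell and 6 rose, with the same counts adjusted over the list alone. ASNS fell by 2.59 ± 0.04 log2, and TRIB3, a pseudokinase gene, and CEBPG changed by -2.58 ± 0.04 and -2.05 ± 0.04. The list passed at adjusted p = 2.1e-06, but adjusted p = 0.096 with an estimated correlation. Of 18 NF-kB and inflammatory genes, 10 fell and 1 rose (adjusted p = 0.0090, and adjusted p = 0.22 with an estimated correlation), with the same counts adjusted over the list alone. IL1A, the gene of a cytokine, fell by 2.62 ± 0.07 log2, and the chemokine genes CXCL2 and CXCL8 changed by -1.91 ± 0.07 and -0.99 ± 0.08. Of 24 fatty acid oxidation genes, 14 fell and 2 rose (adjusted p = 0.00034, and adjusted p = 0.096 with an estimated correlation), again with these counts adjusted over the list alone. Besides FGF21 they included the electron transfer genes ETFDH and ETFB, each at -0.56 ± 0.04.

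Heat shock genes rose, 16 of 21, and 1 fell, with 17 and 1 adjusted over the list alone (adjusted p = 1.4e-07, and adjusted p = 0.096 with an estimated correlation). DNAJA1, a co-chaperone gene, rose by 1.02 ± 0.03 log2 and HSPE1, a mitochondrial chaperonin subunit gene, by 0.75 ± 0.04. Of 20 cholesterol synthesis genes, 13 rose, or 14 adjusted over the list alone (adjusted p = 0.00018, and adjusted p = 0.17 with an estimated correlation). SQLE rose by 1.11 ± 0.05 and MSMO1 by 1.03 ± 0.06. Of 12 metallothionein and metal response genes, 9 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.0036, and adjusted p = 0.096 with an estimated correlation). MT1X, a metal-binding metallothionein, rose by 0.97 ± 0.05, MT1E by 0.68 ± 0.06 and MT2A by 0.37 ± 0.02, the last of which was -0.031 after spike-in centring. Of 38 ribosome biogenesis genes, 20 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.015, and adjusted p = 0.46 with an estimated correlation). POLR1C, a subunit of RNA polymerases I and III, rose by 0.69 ± 0.05 (weakest probe set 0.15).

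**Figure D3:**
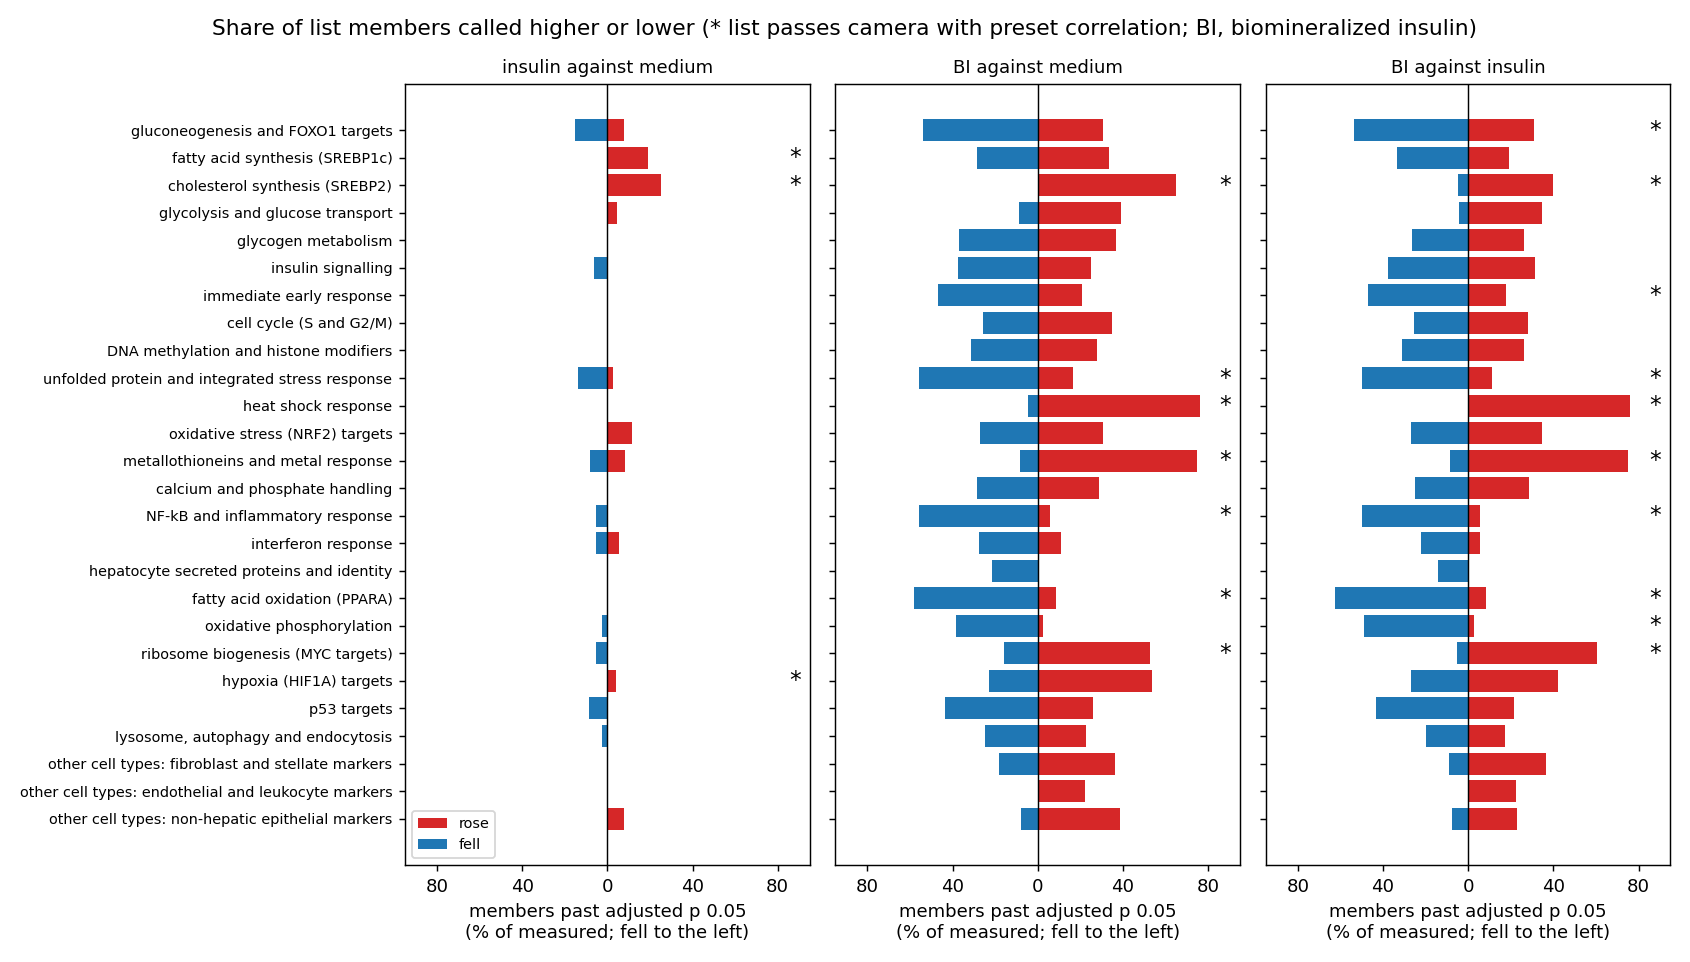
Share of measured members of each of 26 lists that rose (right, red) or fell (left, blue) past adjusted p 0.05, in percent, for the 3 comparisons, with an asterisk on lists that passed camera with the preset correlation. Of 21 heat shock genes 16 rose, and of 36 stress response genes 20 fell, under biomineralized insulin against medium.

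Other lists held changes in both directions and did not pass as lists. Of 32 insulin signalling genes, 8 rose and 12 fell (list adjusted p = 0.44). GRB10 and SOCS2, which restrain receptor signalling, changed by -1.33 ± 0.04 and -1.34 ± 0.08 log2, and SOS1, a RAS exchange factor gene, by -1.04 ± 0.04. Of 13 gluconeogenesis and FOXO1 target genes, 4 rose and 7 fell (list adjusted p = 0.17), with TXNIP, an inhibitor of glucose uptake, at -1.77 ± 0.03 and FOXO1 at -0.84 ± 0.04. Of 61 DNA methylation and histone modifier genes, 17 rose and 19 fell (list adjusted p = 0.65). The histone methyltransferase gene EZH2 fell by 0.93 ± 0.07, and the demethylase gene KDM4A by 0.99 ± 0.07 (weakest probe set -0.53). The acetyltransferase gene KAT2B fell by 0.70 ± 0.05, while the demethylase gene KDM2B rose by 0.63 ± 0.05 (weakest probe set 0.053). DNMT1, the maintenance DNA methyltransferase gene, fell by 0.13 ± 0.03. Of 34 immediate early genes, 7 rose and 16 fell (list adjusted p = 0.065). KLF4 was at -1.72 ± 0.07 (weakest probe set -0.78) and EGR1 at -0.89 ± 0.06 (weakest probe set -0.057). HK1, a hexokinase gene, rose by 0.55 ± 0.04 (weakest probe set 0.20), and was at 0.15 and short of the threshold after spike-in centring. Of 23 glycolysis and glucose transport genes, 9 rose and 2 fell (list adjusted p = 0.11).

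Among the insulin and FOXO1 markers, IRS2, an insulin receptor substrate gene, rose by 0.59 ± 0.05 log2 and IRS1 fell by 0.49 ± 0.06 (weakest probe set -0.067). FASN, fatty acid synthase, rose by 0.52 ± 0.06, while SREBF1, the gene of a lipogenic transcription factor, fell by 0.31 ± 0.05 (weakest probe set -0.022). After spike-in centring IRS2 was at 0.18 and FASN at 0.12, both short of the threshold. PPARGC1A fell by 0.35 ± 0.05 and SOCS3 by 0.20 ± 0.07, with its other probe set of opposite sign, and the call of SOCS3, biomineralized insulin against medium, was lost without medium replicate 2 (adjusted p = 0.072) and without biomineralized insulin replicates 1 and 2 (0.052 and 0.077), in a range of 3.8e-07 to 0.29 over all alternatives. INSR, the insulin receptor gene, was not called (0.11 ± 0.05, adjusted p = 0.11), and 2 of its 4 probe sets had the opposite sign. PCK1 and G6PC1, gluconeogenic genes, and IGFBP1 lay among the dim probe sets. In the fit without a brightness filter PCK1 and G6PC1 were not called (adjusted p = 0.42 and 0.89) and IGFBP1 was called higher (adjusted p = 0.0022), at 5.06 log2 against 4.38 in medium, below the filter.

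Biomineralized insulin against insulin, at the same dose, is the test of the difference between the treatments. INHBE was at least 24.6-fold lower, at 4.32 log2 against 9.36 with insulin, and FGF21 at least 4.52-fold lower, at 3.78 against 6.92, both bounds again against the brightness filter. SLC7A11 differed by -3.07 ± 0.04 log2 and DDIT3 by -2.88 ± 0.06. HSPA1B was higher by 2.74 ± 0.06 and HSPA8 by 1.79 ± 0.04. SPOCK1 was at least 3.39-fold higher, at 6.55 against 4.71, which lay below the filter. TNFRSF10D, a decoy receptor gene, and PER2, a clock gene, were higher by 1.60 and 1.51, although another probe set of TNFRSF10D was at 0.22, and without cross-hybridizing probe sets PER2, biomineralized insulin against insulin, was at 0.0074 (adjusted p = 0.95, the highest of its alternatives, of which the lowest was 1.8e-19). The number of genes changed, biomineralized insulin against insulin, was 5433 of 12240, 2579 higher and 2854 lower, and 636 by at least 1.5-fold (196 higher, 440 lower). The 3' minus 5' signal of GAPDH was 0.20 ± 0.02 log2 with biomineralized insulin and 0.17 ± 0.0045 with insulin (SD, n = 3, two-sided exact permutation p = 0.1, and 0.267 adjusted over 16 tests), and that of actin differed by -0.12 (exact p = 0.3). Centring on the spike-ins moved the median of all genes by -0.39 log2 and gave 165 higher and 9446 lower.

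Heat shock genes, metallothionein and metal response genes, ribosome biogenesis genes and cholesterol synthesis genes were higher with biomineralized insulin than with insulin. Of 21 heat shock genes 16 were higher (adjusted p = 3.7e-09, and adjusted p = 0.063 with an estimated correlation). Of 12 metallothionein and metal response genes 9 were higher and 1 lower (adjusted p = 0.00083, and adjusted p = 0.063 with an estimated correlation). Of 38 ribosome biogenesis genes 23 were higher and 2 lower (adjusted p = 0.00077, and adjusted p = 0.37 with an estimated correlation). Of 20 cholesterol synthesis genes 8 were higher and 1 lower (adjusted p = 0.0015, and adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone, these counts were 16 higher for heat shock, 10 and 1 for metallothioneins and metal response, 25 and 3 for ribosome biogenesis and 8 and 1 for cholesterol synthesis.

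Among the lists that were lower, 18 of 36 stress response genes were lower and 4 higher (adjusted p = 2.7e-07, and adjusted p = 0.063 with an estimated correlation). Of 24 fatty acid oxidation genes 15 were lower and 2 higher (adjusted p = 0.00017, and adjusted p = 0.063 with an estimated correlation). Of 39 oxidative phosphorylation genes 19 were lower and 1 higher (adjusted p = 0.0032, and adjusted p = 0.51 with an estimated correlation). Of 18 NF-kB genes 9 were lower and 1 higher (adjusted p = 0.0047, and adjusted p = 0.23 with an estimated correlation). Of 34 immediate early genes 16 were lower and 6 higher (adjusted p = 0.018, and adjusted p = 0.37 with an estimated correlation). Of 13 gluconeogenesis and FOXO1 target genes 7 were lower and 4 higher (adjusted p = 0.025, and adjusted p = 0.37 with an estimated correlation). For the list gluconeogenesis and FOXO1 targets, biomineralized insulin against insulin, the adjusted p was 0.051 without insulin replicate 3 and 0.059 with no brightness filter, in a range of 8.3e-06 to 0.37 over all alternatives. Adjusted over the list alone, the counts were 19 lower and 4 higher for the stress response, 16 and 2 for fatty acid oxidation, 20 and 1 for oxidative phosphorylation, 9 and 1 for NF-kB, 19 and 6 for immediate early genes and 7 and 4 for gluconeogenesis.

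How far the treatments moved the same genes was asked by comparing their changes against medium. Of the 300 genes called under insulin, 286 moved in the same direction under biomineralized insulin, 277 of them past the threshold, and 245 also differed past the threshold between the treatments in that direction. Genes selected against the same medium arrays share their chance values: in 100 simulations with both groups unchanged, the 300 genes of lowest p had the same direction in 269.6 cases on average, or 89.9 percent beside the observed 95.3 percent, and 0.03 of them were called in both. With the insulin changes as estimated and biomineralized insulin unchanged, 1092.8 genes were called on average, and 67.9 percent of them had the same direction. Those estimates hold chance differences too, and the called set is larger than the observed 300. The 67.9 percent is therefore not a matched value for the observed 95.3 percent. MSMO1 rose by 0.41 log2 under insulin and 1.03 under biomineralized insulin, with 0.089 and 0.69 for its weakest probe set. INSIG1 rose by 0.36 and 1.78, with 0.23 and 0.67 for its weakest probe set. GDF15 changed by -0.60 and -2.44, with -0.070 and -0.11 for its weakest probe set. Of all genes tested, 69.7 percent had the same sign in both comparisons, beside 66.6 percent for simulated unchanged groups that share the medium arrays. Across genes, which are not independent replicates, the changes correlated at 0.533, beside 0.499 in those simulations. Their covariance was 0.0173, beside 0.0026. Both simulated groups were unchanged, while 6230 of 12240 genes were called in biomineralized insulin against medium. In unchanged groups the shared medium arrays alone set the correlation and the share of equal signs. The 0.499, 66.6 percent and 89.9 percent are therefore not matched values for the observed ones. The covariance, which keeps the size of the changes, was larger than in the simulations. Genes called higher in both numbered 135 and lower in both 142, where independent lists would share 39.2 and 37.1, and 10 were called in opposite directions, where 76.3 would be. The values for independent lists leave out the shared medium arrays. The 3 medium arrays cannot be divided into parts of at least 2, so part of the overlap may come from them.

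**Figure D4:**
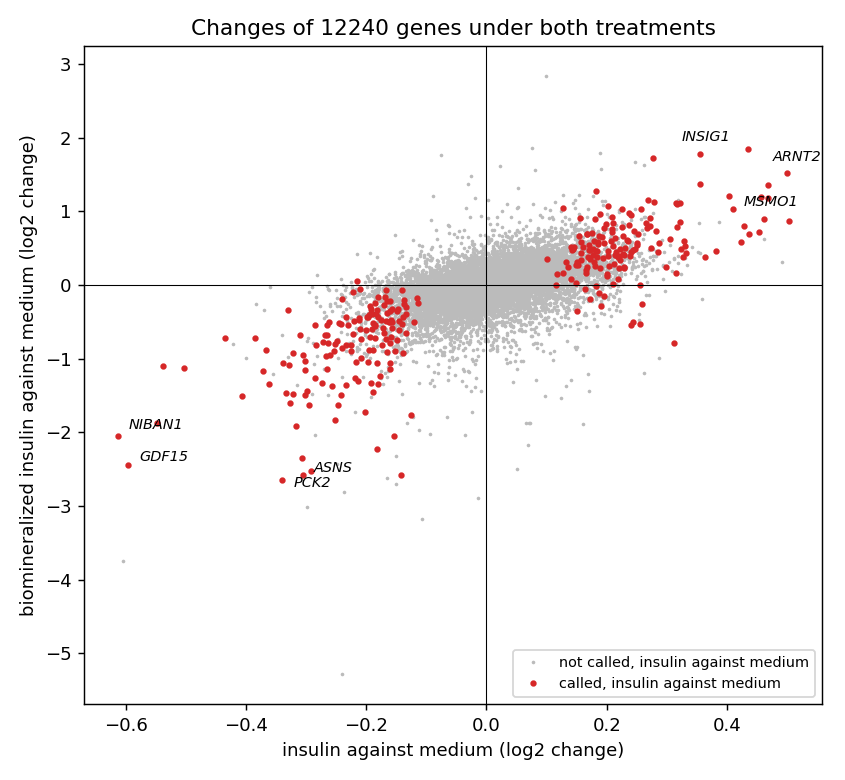
Log2 change under insulin (horizontal) and under biomineralized insulin (vertical), each against medium, for 12240 genes, with genes called under insulin in red. Of the 300 red points, 286 lie in the quadrants of equal sign, and the vertical axis spans more than the horizontal.

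Hepatocyte genes were dim on the arrays of every group, as a description only, since levels of different probe sets are not on one scale. Of 37 listed genes with a probe set, 23 lay in the dimmest 40 percent. The median percentile of the list was between 20.7 and 24.1 on the 9 arrays. It was 44.5 to 48.4 for non-hepatic epithelial, 45.1 to 48.4 for fibroblast and stellate and 30.5 to 35.6 for endothelial and leukocyte markers. ALB (albumin) had a mean of 3.40 ± 0.16 log2 (SD, 9 arrays), AFP (alpha-fetoprotein) 2.93 ± 0.09 and APOB (apolipoprotein B) 2.78 ± 0.12. As means of the 9 arrays, CPS1, a urea cycle gene, was bright at 13.11 ± 0.09. So were KRT18, an epithelial keratin gene, at 12.43 ± 0.05 and KRT7, a keratin gene of the non-hepatic epithelial list, at 11.99 ± 0.08. VIM, an intermediate filament gene of the fibroblast and stellate list, was at 13.11 ± 0.13. Of 14 hepatocyte genes bright enough to test, 3 fell under biomineralized insulin against medium (list adjusted p = 0.91, with a median of 0.09 log2 where the test's direction was down), CYP1A1 by -0.89 ± 0.09 (other probe set -0.24), CEBPA by -0.35 ± 0.07 and CPS1 by -0.18 ± 0.03. Marker lists of other cell types did not pass either (adjusted p = 0.30 for fibroblast and stellate, 0.29 for endothelial and leukocyte and 0.19 for non-hepatic epithelial markers). Of 11 fibroblast and stellate markers 4 rose and 2 fell, of 9 endothelial and leukocyte markers 2 rose, and of 13 non-hepatic epithelial markers 5 rose and 1 fell, the same adjusted over the list alone. FN1, the fibronectin gene, rose by 0.92 ± 0.10 log2, and DCN and VIM by 0.32 and 0.27, although after spike-in centring DCN was at -0.085 and VIM at -0.13. NKX2-1 rose by 0.59 ± 0.07, with its other probe set at -0.093 and a value of 0.18, short of the threshold, after spike-in centring.

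**Figure D5:**
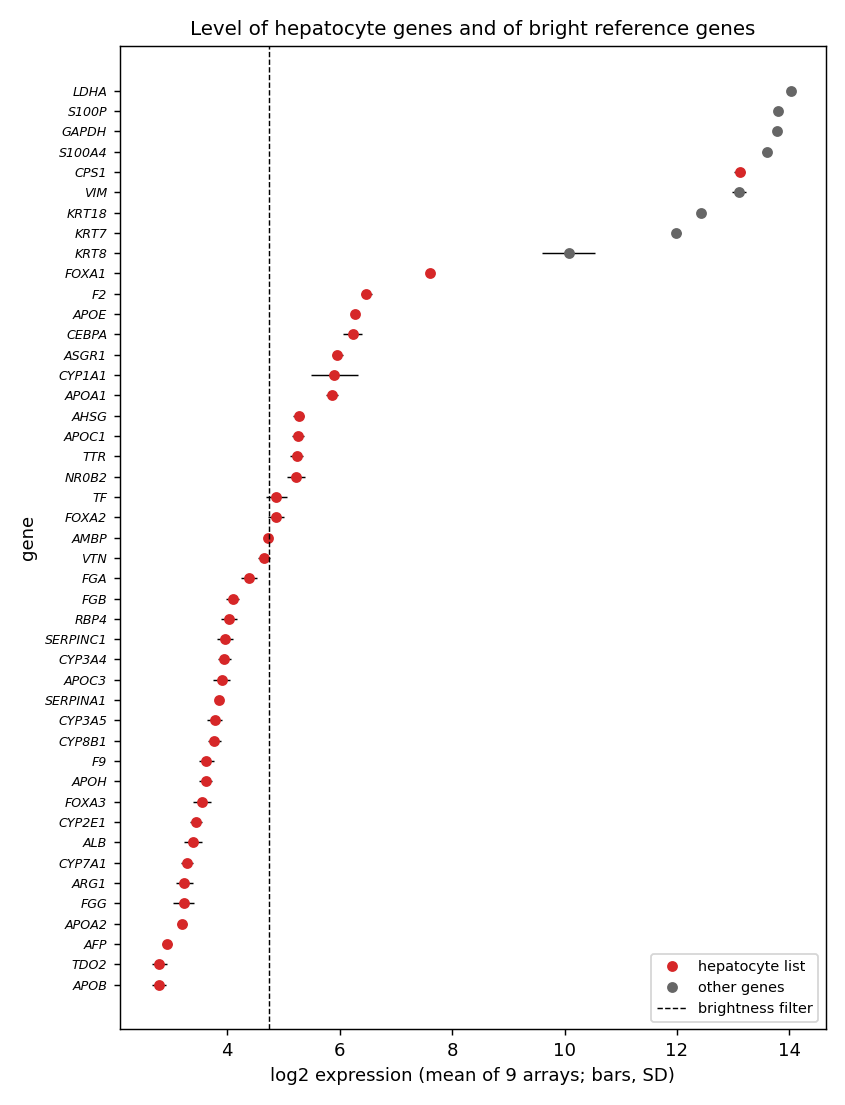
Mean log2 expression over 9 arrays (points, with bars for the SD) of the 37 hepatocyte list genes (red) and of 8 other genes chosen as bright after the data were seen (grey), with a dashed line at the brightness filter of 4.74. Of the hepatocyte genes CPS1 lies at 13.1, and 23 lie below the line.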

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

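The hepatocyte tests, the tests on hybridization controls and that of messenger RNA amount were chosen after the results were seen. The poly-A spike-in controls stood out as a signal in data outside the gene measurements. All 24 of their probe sets were brighter on biomineralized insulin arrays, by a median of 0.424 log2, and the array means averaged 7.62 ± 0.16 against 7.22 ± 0.07 in medium (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, and 0.267 adjusted over 16 tests). Stronger hybridization, staining or scanning is argued against by the 18 hybridization controls, whose median change was 0.0015 (95% interval over probe sets, not arrays, -0.021 to 0.031). Their array means averaged 10.616 ± 0.013 with biomineralized insulin and 10.612 ± 0.011 in medium (SD, n = 3). The 11 hybridization controls between 8.32 and 10.83 log2 had a median change of 0.031 (95% interval over probe sets -0.0064 to 0.036). They argue against a shift of all features through normalization for the 6 spike-in probe sets in that range, whose median change was 0.41. For the 18 dimmer ones it stays open: brightness-matched probe sets had a median change of 0.0067, but near-identical distributions on all arrays hold that value near 0 in any case, so the bound set beforehand was wrong. Less messenger RNA per unit of total RNA in these cells, or unequal amounts of RNA or spike-in in the labelling reaction, could each give 0.424, and cannot be told apart from the deposited values.

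The low level of hepatocyte genes in all groups is set out here because no array of the parental line was analysed. The median percentile of ribosomal protein genes was at least 99.7 on each of the 9 arrays, which argues against arrays that failed as a whole. Compression that keeps ranks could not by itself give the low percentiles of the hepatocyte list. The medium arrays, which received neither treatment, had a median percentile of 20.7 to 24.1. It was 22.1 to 22.6 with insulin and 22.1 to 23.1 with biomineralized insulin. The level was thus as low without treatment, which argues against a loss through the treatments. At most 6 of 37 genes lay above the array median on a medium array. Cells other than hepatoma cells, or a derivative that lost the hepatocyte programme, could both give this, and cannot be told apart without arrays of the parental line.

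Probe sets and genes outside the tested set held differences too. Of 2353 brighter probe sets with no gene or several genes, 1048 were called between biomineralized insulin and medium. Of 5892 genes below the brightness filter, 252 were called higher and 85 lower in a fit without the filter.

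Each comparison of 6 arrays allows 10 splits into 3 and 3, too few for a share under 0.05, and 1 split, the real one, gave as many called genes in each. The real value and the highest of the other splits were 300 and 185 for insulin against medium. They were 6230 and 0 for biomineralized insulin against medium, and 5433 and 0 for biomineralized insulin against insulin. The other splits mix arrays of both groups, so a large real difference enters their spread and holds their counts down. Those counts are therefore no measure of false calls. That holds for low counts and does not account for the 185 called in another split of insulin against medium. A mixed split also keeps part of any real difference. How many of the 300 calls come from differences between single arrays was not tested.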

How the results depend on the processing

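Centring on poly-A spike-ins was chosen after the data were seen. The number of genes changed, insulin against medium, 300, became 152 with only the 6 arrays compared, 190 with median centring, 177 with the probe set of largest variance, 199 without cross-hybridizing probe sets, 37 with eBayes without trend, 604 with array weights, 66 at adjusted p under 0.01, 2 at 1.5-fold and 7 centred on poly-A spike-ins (14.3 percent higher, against 51). Fewer genes tested or a stricter threshold account for part of this by construction. Otherwise the cause was not tested. Leaving out single arrays gave 57 to 425. The number of genes changed, biomineralized insulin against medium, 6230, became 870 at 1.5-fold and 9393 with spike-in centring (2.91 percent higher, against 50.4), with 5504 to 6291 when single arrays were left out. The number of genes changed, biomineralized insulin against insulin, 5433, became 636 and 9611 (1.72 percent higher, against 47.5), with 4855 to 5556. With the replicate block the counts were 226, 6082 and 5302, and lists called were 3, 7 and 10; only 1 of 9 same-numbered pairs correlated above 0.1, and 1 of 9 arrays correlated best with its own number. Camera with an estimated correlation called 0 lists in each comparison, against 3, 7 and 10 (unadjusted p under 0.05 for 2, 5 and 5), and fry, which asks a different question, gave 2, 23 and 23; without single arrays they were 2 to 4, 7 to 8 and 10 to 10. The covariance of the treatments' changes beyond shared controls, 0.0147, was 0.0104 without the brightness filter, more than its jackknife error of 0.00409 away, and 0.0130 to 0.0184 without single arrays.

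Under the alternatives other than spike-in centring, 253 called gene values gave 6022 recomputed values, of which 5671 kept direction and call, 343 lost the call and 8 changed sign. Of 320 values for 20 called lists, 290 kept direction and call, 30 lost the call and 0 changed sign. Lists were not retested with spike-in centring. There, in biomineralized insulin against medium, medians were -0.020 for heat shock, -0.026 for metallothioneins and metal response, -0.20 for cholesterol synthesis and -0.29 for ribosome biogenesis. Against insulin they were -0.011, -0.13, -0.28 and -0.25. Relative to the median of all genes (-0.38 and -0.37), all 20 lists kept their direction. For the log2 values that changed sign, beyond the common shift of spike-in centring, the cause was not tested. With array weights, in insulin against medium, INSR was at 0.013. Centred on poly-A spike-ins, in biomineralized insulin against medium, sign changes were APOC1 -0.21, ATP5MC1 -0.22, AURKA -0.15, BST2 -0.24, DCN -0.085, GSK3A -0.17, INSR -0.30, MT2A -0.031, MUC1 -0.14, S100A2 -0.022 and VIM -0.13. Centred on poly-A spike-ins, in biomineralized insulin against insulin, sign changes were CAMKK2 -0.13, CCNB1 -0.063, DCN -0.15, ESR1 -0.19, FASN -0.023, GSK3A -0.13, GYS1 -0.0059, INSR -0.27, NKX2-1 -0.017, S100A2 -0.13, SLC2A1 -0.11, TAGLN -0.11 and VIM -0.16. Without cross-hybridizing probe sets, in insulin against medium, VASH2 was at -0.011. Without cross-hybridizing probe sets, in biomineralized insulin against insulin, sign changes were ESR1 -0.062, RRM2 0.18 and TAGLN -0.052. With the mean of a gene's probe sets, the value of MXI1, insulin against medium, was -0.0086, that of INSR, biomineralized insulin against medium, was -0.0082 and that of NDUFS8, biomineralized insulin against medium, was 0.0029. With the probe set of largest variance, in insulin against medium, PPARGC1A was at -0.062. With the probe set of largest variance, in biomineralized insulin against medium, sign changes were INSR -0.12 and NDUFS8 0.17. With the probe set of largest variance, in biomineralized insulin against insulin, sign changes were ESR1 -0.062, INSR -0.059 and RRM2 0.18. With quantile normalization, in insulin against medium, INSR was at 0.00045. Without medium replicate 3, in insulin against medium, INSR was at 0.010. Without insulin replicate 3, in insulin against medium, sign changes were INSR 0.011, IRS2 -0.023 and SOCS3 -0.0050. Without single arrays, INSR ranged from -0.048 to 0.011, IRS2 from -0.023 to 0.082 and SOCS3 from -0.0050 to 0.11 for insulin against medium. The number of arrays limits the precision, and signal over background was not examined.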

Other observations

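All tests in this part were chosen after results were seen, except that of the chaperonin and prefoldin genes. The lists in this part were written after some results had been seen, among them the changes of WARS1 under insulin and of PER2, TEF and RORA, and the genes named here were chosen after their values were seen. Aminoacyl-tRNA synthetase and amino acid transporter genes, most of them known ATF4 targets, fell as a group: 21 of 22 under biomineralized insulin against medium (median -0.93 log2, adjusted p = 3.1e-19, and adjusted p = 0.034 with an estimated correlation) and 13 of 22 under insulin (median -0.17, adjusted p = 1.6e-26, and adjusted p = 0.016 with an estimated correlation). CARS1 and AARS1, the cysteinyl- and alanyl-tRNA synthetase genes, changed by -1.84 and -1.48 log2 under biomineralized insulin and by -0.25 and -0.32 under insulin. VARS1 did not pass the threshold (-0.030 log2 under biomineralized insulin).

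Clock genes moved in both directions under biomineralized insulin. Of 13 measured, 7 rose and 4 fell (list adjusted p = 0.29). TEF and NR1D2 rose by 1.36 and 0.75 log2, and BMAL1 and NFIL3 changed by -1.44 and -1.37. Under insulin, 1 of 13 rose.

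One hypothesis is that the fall of the stress response list under biomineralized insulin lies in its ATF4 branch. The amino acid list, which shares no gene with the stress list, fell with an unadjusted camera p of 7.7e-20, which is consistent with it. Without WARS1, the member seen to fall under insulin before the list was written, 20 of the other 21 genes fell, with an unadjusted camera p of 5.3e-19 (0.0084 with an estimated correlation). A fall of the endoplasmic reticulum chaperone branch is argued against: its 17 members had a median change of 0.011 log2 (95% interval over genes, not arrays, -0.048 to 0.145), against -1.07 for the remaining 19 members. Past the threshold, 5 of the 17 rose and 3 fell, and 1 of the 19 rose and 17 fell. The list was divided in this way after its result was seen. HSPA5, the main chaperone gene of that branch, was at 0.0035 log2. The mineral component and the insulin were not separated by the design, so what lowers these genes stays open.

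A second hypothesis is that the heat shock rise is part of a general rise of protein folding genes. Chaperonin and prefoldin genes, of which 8 of 14 rose and 1 fell, missed the threshold as a list, with an unadjusted camera p of 0.053. A p that misses the threshold does not show that the list stayed level, so the bound set beforehand for excluding this hypothesis was wrong, and it stays open.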
